A study of Mus musculus with 12 samples.

How the data were processed

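RNA was sequenced from sorted mouse Treg cells of 2 genotypes, with and without stimulation, in 12 libraries of 3 per group. Per the labels' protocols, libraries were made from 600 ng of RNA with a kit that selects polyadenylated RNA and keeps its strand. FastQC, STAR, featureCounts of Subread and DESeq2 are named in the submitters' processing notes without versions or roles, and the submitters' build is mm10. The strand setting of the counting, the handling of reads that match several genes and the annotation release are not given in the sources used here.

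The deposited table holds 1 RPKM value per gene and library (reads per kilobase of merged exons scaled to the library's assigned reads) and the exon length, chromosome, start, end and strand of each gene. Products of RPKM and length were multiples of 1 step in each library. Divided by that step, which is the value of 1 read, 100% of them were within 0.01 of a whole number, and these reads summed to each library's assigned reads. They ran from 23154208 to 26860948 in unstimulated WT, 22731823 to 26439126 in unstimulated KO, 26153778 to 28586953 in stimulated WT and 27340975 to 32055383 in stimulated KO. Of 24421 entries, 27 carried a spreadsheet date in place of a gene symbol and were left out of the tests. They held between 0.185% and 0.284% of each library's reads, and the RPKM values were used as deposited. The table has 0 mitochondrially encoded symbols, and 54 symbols lie on more than 1 chromosome. To look for a library deposited under 2 names, the reads of 12 pairs of replicates were compared, and chi-square per degree of freedom was from 5.86 to 39.92. This sets the pairs against counting error only and says nothing of the source of their differences.

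Because the table turned out to hold RPKM and not counts, the count test planned before the data were examined was replaced by limma 3.58.1 (moderated statistics with a mean trend, in R 4.3.3) on log2(RPKM + 1). The planned count alternatives with DESeq2 and edgeR were not run. Genes with at least 1 RPKM in 3 or more libraries were tested (10406 genes). One model with a mean for each of the 4 groups was fitted to the 12 libraries, with 8 residual degrees of freedom, and gave 5 contrasts: KO against WT in each state, stimulated against unstimulated in each genotype, and their interaction. P-values were adjusted by Benjamini-Hochberg within a contrast, with a threshold of 0.05. Of 34 gene lists fixed before the data were examined, 32 had at least 5 tested members. They were tested with camera of limma at a preset correlation of 0.01 on log2 CPM worked out from the reads (prior count 2), and again with an estimated correlation and with fry. The estimated correlation was 0.005 for chemokine receptors, integrins and trafficking and -0.011 for Th17-type genes, under the preset value. For these lists a larger adjusted p with the estimate cannot be put down to a higher correlation. The bound for reading library numbers as pairs was that every same-numbered pair deviated from its group means together with a correlation over 0.1. This held for KO unstimulated and stimulated libraries (0.274, 0.19 and 0.11), but not for WT ones (0.075, 0.134 and 0.146) or for WT and KO libraries of 1 state. The main fit used no pairs. Alternative fits blocked by number over all 12 libraries, or by genotype and number with WT ones included.

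Genes to name were chosen by a rule set before the data were examined. Batf came first, followed by the 10 largest rises and 10 largest falls of each genotype contrast. These had to pass the threshold, have a mean of at least 5 RPKM and show no overlap between the 3 libraries of each group, which chance gives for 10% of genes. For the stimulation contrasts and the interaction 6 of each were taken, without the overlap condition for the interaction. Predicted gene names and receptor variable segments were skipped. Up to 4 members of each list with the smallest adjusted p were added, with 17 genes of Treg identity and lipid or sugar metabolism that were always included. Some genes in the text lie outside this rule: the Y-linked genes, Cd74, Rn45s, Ltb, Rpl23a and the genes named as examples of a list beyond its 4 members were chosen after their values were seen. Where neither the reported fit nor an alternative called a gene, the gene was counted as the same.

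The fit was tested on simulated reads for the real genes with 50 genes at each of 4 fold changes. In the unstimulated genotype contrast (10334 genes) it recovered 34% at 1.25-fold, 98% at 1.5-fold, 100% at 2-fold and 100% at 4-fold, with 9 calls among 10134 unchanged genes. In the stimulated contrast (10333 genes) it recovered 34%, 100%, 98% and 98%, with 8 calls among 10133 unchanged genes. Lists shifted 1.5-fold were recovered in 10 of 10 simulations, with 0 calls among 247 lists without shifted genes. The changed genes were drawn from those with a mean of at least 2 RPKM, so recovery among genes with less RNA was not measured. Each gene was drawn independently with 1 common dispersion (0.00528), so recovery may differ for genes that vary more between libraries. The simulated lists also held no correlation between genes. In the data the estimated correlation was as high as 0.452, for cholesterol synthesis. The simulation therefore cannot tell how often camera at the preset correlation calls unshifted lists here. The alternatives changed the pseudocount, the filter, the libraries fitted, the replicate block, the set test and each library in turn. Others, chosen after the data were seen, were rescaling by median ratios, limma-voom on the reads, a term for the 4 libraries with Y-linked transcripts, leaving those 4 out, and leaving out both KO libraries numbered 1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 read the table and drew the figures.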

Results

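The series compared regulatory T cells (Treg cells, CD4 T cells that restrain immune responses) from wild-type (WT) mice and from mice lacking Batf (KO), an AP-1 family transcription factor of lymphocytes. Its title names the function and the metabolism of Treg cells as the subject. Sorted cells of C57BL/6 mice aged 7 weeks were profiled by RNA-seq without stimulation or after 48 h on plate-bound antibodies to CD3 and CD28 (5 µg/ml) with IL-2 (200 U/ml). CD3 is the signalling part of the T cell receptor, CD28 is its costimulatory partner, and IL-2 is a growth factor of Treg cells. Each of the 4 groups held 3 libraries. Between 22731823 and 32055383 reads per library were assigned to genes, and 10406 genes with at least 1 RPKM in 3 or more libraries were tested. RPKM values below are group means ± SD over n = 3 libraries. Fold changes are limma estimates on the log2(RPKM + 1) scale, which understates the change of genes with low values. Nothing in the labels says that the 3 libraries of a group came from separate animals, and the p-values measure the spread between these libraries. Y-linked transcripts and Xist set WT library 3 apart from WT libraries 1 and 2, so the WT libraries did not all come from 1 animal, while the KO spread may be technical.

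Batf (chromosome 12, 85686720 to 85709087, plus strand, mm10) was lower in every KO library than in any WT library. Its RPKM was 102.67, 93.26 and 90.03 in unstimulated WT libraries 1 to 3 and 46.91, 32.99 and 25.94 in unstimulated KO libraries 1 to 3. After stimulation it was 133.95, 125.33 and 127.77 in WT and 26.49, 21.2 and 17.98 in KO. The log2 fold change was -1.45 (SE 0.17, limma adjusted p = 0.000189) without and -2.52 (SE 0.17, adjusted p = 1.17e-06) with stimulation. The values sum reads over all exons of the gene and the deleted exons are not given in the sources used here, so reads from exons left in place count toward the KO values. The first principal component of the log2 values held 86.5% of the variance and parted stimulated from unstimulated libraries, and the second held 5.8%. The Y-linked transcripts Ddx3y, Kdm5d, Uty and Eif2s3y were abundant in WT libraries 1 and 2 of both states, with Eif2s3y at 38.56 to 57.72 RPKM. In the other 8 libraries Eif2s3y reached at most 0.07 RPKM, so every KO library and WT library 3 lacked these transcripts. Xist was at 1.07 to 2.86 RPKM in those 8 libraries and at most 0.01 in WT libraries 1 and 2. By these transcripts WT libraries 1 and 2 came from male cells, and WT library 3 and every KO library from female cells. Sex was thus partly confounded with genotype.

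**Figure D1:**
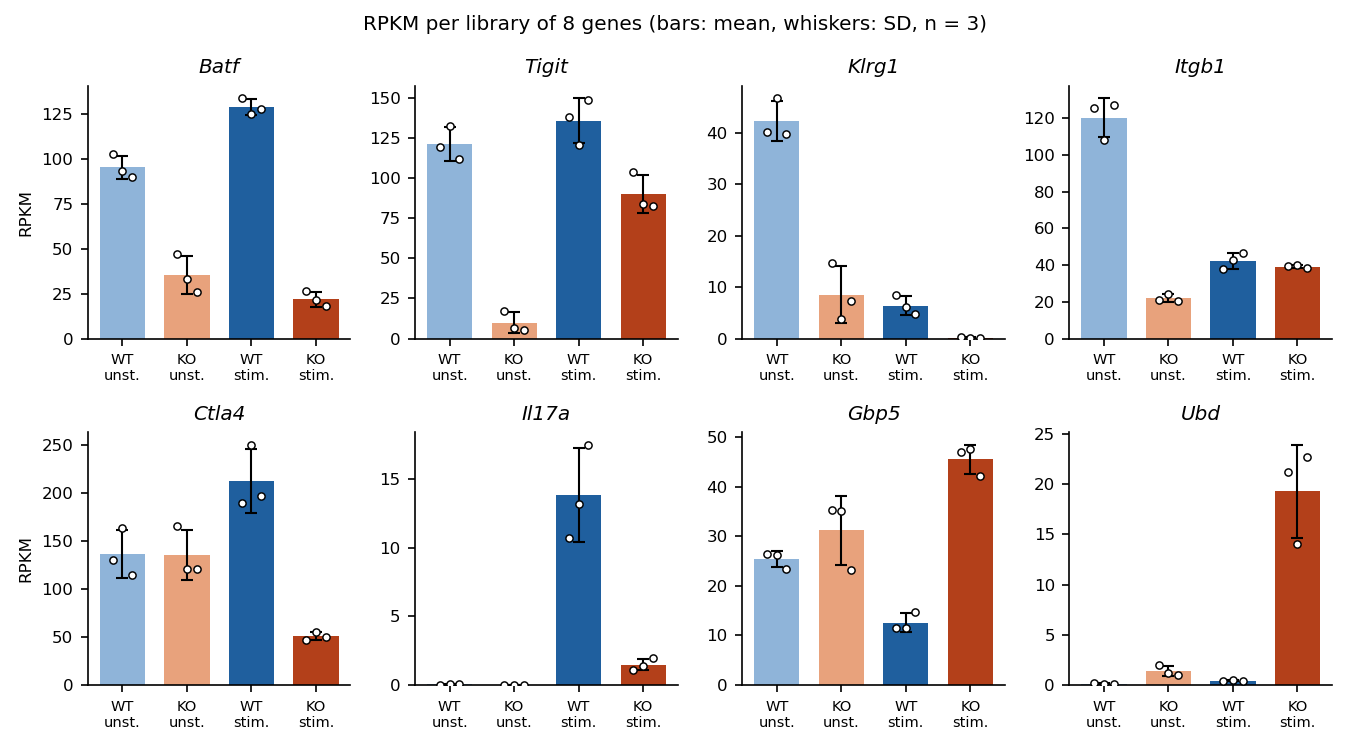
RPKM (y axis, linear from 0) of 8 genes in the 4 groups. Bars are means, whiskers are SDs, and points are the 3 libraries of each group; Batf ranged from 90.03 to 133.95 RPKM in WT libraries and from 17.98 to 46.91 RPKM in KO libraries.

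Without stimulation, KO Treg cells held less RNA for Tigit, Itgb1, Klrg1 and Ccr4 and more for Plac8 and Dgat2 than WT cells. Tigit, an inhibitory receptor, fell from 121 ± 10.4 to 9.89 ± 6.39 RPKM (n = 3, log2 fold change -3.64, SE 0.27, limma adjusted p = 3.08e-06). Itgb1, the integrin beta 1 chain, fell from 120.5 ± 10.7 to 22.1 ± 1.94 RPKM (log2 fold change -2.40, SE 0.09, adjusted p = 8.03e-09). Klrg1, a marker of terminally differentiated Treg cells, fell from 42.2 ± 3.92 to 8.55 ± 5.57 RPKM, and the chemokine receptor Ccr4 fell from 45.2 ± 6.56 to 8.39 ± 2.06 RPKM. In the other direction, Plac8 rose from 22.2 ± 8.30 to 88.3 ± 12.9 RPKM and Dgat2, an enzyme of triglyceride synthesis, rose from 5 ± 0.531 to 16.1 ± 2.69 RPKM.

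Other large falls were those of Ttc39c (log2 fold change -2.84), the cytotoxic protease Gzmb (-2.18), the integrin chain Itgae (-2.17), the calcium-binding protein S100a4 (-2.13), Adap1 (-2.02) and the opioid precursor Penk (-1.88). Itgae rested on uneven KO libraries, with 29.75 RPKM in library 1 against 4.26 and 5.24 in libraries 2 and 3, and its adjusted p of 0.0149 became 0.0576 when KO library 3 was left out, 0.0658 with the 6 libraries fitted alone, 0.0577 with a term for Y-linked transcripts and 0.299 without the 4 libraries that hold them. Other large rises were those of the guanylate-binding protein gene Gbp2b (2.17), the costimulatory ligand Cd80 (1.81), the ligand Wnt10a (1.68), Myo6 (1.67), the NADPH oxidase subunit Ncf1 (1.65), Igfbp7 (1.62), the amino acid transporter Slc43a1 (1.61) and Lad1 (1.46). Gbp2b resembles Gbp2 in sequence, and how reads shared between such copies were assigned is not given in the sources used here. The lineage factor Foxp3 was at 70.2 ± 4.99 in WT and 58.4 ± 6.83 RPKM in KO (log2 fold change -0.27, adjusted p = 0.0772), and passed only without KO library 2 (adjusted p = 0.0158) among the fits that left out 1 library. Il2ra (145 ± 1.14 and 146 ± 12.9 RPKM) and Ctla4 (136 ± 24.9 and 136 ± 26.0 RPKM) did not pass the test.

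Of 30 tested genes in a list of effector and tissue Treg cells, 19 fell and 2 rose (21 and 2 adjusted over the list alone). The falls included Icos (log2 fold change -1.71), Ccr2 (-1.49), Il18r1 (-1.45) and Cxcr3 (-1.21), and Irf4, the partner factor of Batf, was one of the rises (0.58, SE 0.10). The list was lower in KO by camera (adjusted p = 3.43e-13), and the adjusted p was 0.0938 with an estimated correlation. Chemokine receptors, integrins and trafficking genes were also lower, with 10 of 27 falling and 1 rising (11 and 1 adjusted over the list alone), among them Gpr15 (-2.81), a homing receptor for the colon. This list kept its call both ways (adjusted p = 1.16e-05, and adjusted p = 0.0292 with an estimated correlation). In the Treg core list, 10 of 27 fell and 3 rose (11 and 4 adjusted over the list alone), including falls of Nrp1 (-1.47) and Ikzf2 (-0.63). Its camera adjusted p was 0.00453, or adjusted p = 0.617 with an estimated correlation. The Th17-type list had 6 of 11 genes lower and 0 higher (6 and 0 adjusted over the list alone), among them Rora (-1.18) and Ahr (-0.88), with an adjusted p of 0.017, or adjusted p = 0.204 with an estimated correlation. Of the costimulatory and inhibitory receptors, 10 of 23 fell and 3 rose (11 and 3 adjusted over the list alone; adjusted p = 0.0244, and adjusted p = 0.398 with an estimated correlation). These lists share members, so 1 gene can count in several, here and in the later contrasts. The effector and tissue Treg list shares Ccr2, Ccr4, Ccr6, Ccr8, Cxcr3, Cxcr6 and Itgae with the trafficking list. It shares Icos, Tigit and Tnfrsf18 with both the costimulatory and the Treg core list. It also shares Tnfrsf9 and Tnfrsf1b with the costimulatory list, and Gzmb, Il10 and Itgae with the Treg core list. With the Th17-type list it shares Rora, Ccr6 and Cxcr6.

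Part of the cell cycle list moved the other way without stimulation. Of 36 cell cycle genes, 14 rose and 0 fell in KO (17 and 0 adjusted over the list alone). E2f2, a transcription factor of S phase entry, rose from 21.3 ± 1.34 to 37.7 ± 4.34 RPKM, the mitotic ubiquitin-conjugating enzyme Ube2c from 39.2 ± 4.62 to 62.6 ± 5.61, and the replication helicase subunit Mcm7 from 72.7 ± 4.19 to 87.6 ± 1.09 (not called with the 6 libraries fitted alone, adjusted p = 0.0526). The camera adjusted p of the list was 1.41e-11, and the adjusted p was 0.218 with an estimated correlation. Amino acid transport, serine and one-carbon genes had 6 of 24 higher and 0 lower (8 and 0 adjusted over the list alone), including Slc7a5 (log2 fold change 0.41) and Shmt2 (0.37), with an adjusted p of 9.01e-05, or adjusted p = 0.398 with an estimated correlation. Nucleotide and polyamine synthesis had 4 of 25 higher and 2 lower (4 and 3 adjusted over the list alone; adjusted p = 0.0277, and adjusted p = 0.54 with an estimated correlation). Interferon response genes had 4 of 28 higher and 0 lower (5 and 0 adjusted over the list alone), with Iigp1 at 0.87 and Igtp at 0.48 (adjusted p = 0.00888, and adjusted p = 0.398 with an estimated correlation). Oxidative phosphorylation (0 of 43 genes called) and ribosome biogenesis (0 of 25) were called higher as lists only, with median log2 fold changes of 0.13 and 0.11, again with 0 called adjusted over the list alone. Their adjusted p of 1.16e-05 and 0.0153 became adjusted p = 0.54 and adjusted p = 0.617 with an estimated correlation. Heat shock and unfolded protein genes had 7 of 19 lower and 1 higher (12 and 1 adjusted over the list alone; adjusted p = 0.00453, and adjusted p = 0.398 with an estimated correlation).

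Markers of other cells were present beside these groups. Lyz2, a myeloid transcript, was at 17.2 ± 2.14 RPKM in unstimulated WT and 14.8 ± 2.50 in KO. Cd74, a member of the B cell list that is not made by B cells alone, was at 115 ± 11.4 and 157 ± 40.1 RPKM. Neither passed the test, although Cd74 did without KO library 3 (adjusted p = 0.0356), with a replicate block over the 12 libraries (adjusted p = 0.0237), after median-ratio rescaling (adjusted p = 0.0454) and by limma-voom on reads (adjusted p = 0.0284). Of 14 myeloid genes, 5 fell in KO, including Cebpa (4.32 ± 0.82 to 0.406 ± 0.157 RPKM), C1qb and C1qc, and 1 rose (Xcr1, 0.274 ± 0.137 to 2.31 ± 0.133 RPKM). No B cell, CD8 T cell, NK cell, myeloid or conventional CD4 T cell list was called, with adjusted p of 0.103, 0.908, 0.759, 0.237 and 0.482. Reads from the ribosomal precursor Rn45s made up 0.438% ± 0.128 of reads in unstimulated KO and 0.285% ± 0.026 in unstimulated WT (n = 3 each).

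In all, 453 genes were higher and 607 lower in unstimulated KO at a limma adjusted p under 0.05 (10.2% of 10406), of which 44 and 63 changed by at least 1 on the log2 scale. Rescaling by median ratios of reads gave 677 higher and 500 lower, so the balance of directions depended on the scaling. Leaving out WT library 1 gave 242 higher and 326 lower, leaving out WT library 3 gave 239 and 337, and leaving out KO library 3 gave 396 lower. Fitting the 6 libraries alone gave 196 and 321, leaving out both KO libraries numbered 1 gave 298 higher, a term for Y-linked transcripts gave 399 lower, and leaving out the 4 libraries with those transcripts gave 41 and 57 and ended 32 of the 75 named calls and values checked. Among these were Batf, Klrg1, Cd80 and Wnt10a, whose log2 fold changes were then -1.37, -2.26, 1.85 and 1.76 (-1.45, -2.34, 1.81 and 1.68 with all libraries), with fewer libraries to measure the spread.

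After 48 h of stimulation, KO Treg cells held less RNA for Ctla4, Il17a, Il10 and Ccr8 than stimulated WT cells. Ctla4, the inhibitory receptor that Treg cells use against antigen-presenting cells, was at 213 ± 33.3 RPKM in WT and 51.0 ± 4.24 in KO (n = 3, log2 fold change -2.03, SE 0.15, limma adjusted p = 1.69e-06). Il17a, an inflammatory cytokine, was at 13.8 ± 3.42 in WT and 1.49 ± 0.421 RPKM in KO (log2 fold change -2.56, SE 0.15). The anti-inflammatory cytokine Il10 was at 44.6 ± 5.27 and 18.6 ± 6.25 RPKM (-1.26, SE 0.20, adjusted p = 0.000838), and the chemokine receptor Ccr8 at 417 ± 13.0 and 145 ± 8.92 RPKM (-1.52, SE 0.10). Ubd, an interferon-inducible ubiquitin-like protein, went the other way, from 0.443 ± 0.0298 to 19.3 ± 4.63 RPKM (3.79, SE 0.17, adjusted p = 4.81e-08).

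Among the largest falls were Ttc39c (log2 fold change -3.55), Klrg1 (-2.61), the transcription factor Maf (-2.20), the chemokine receptor Cxcr6 (-2.17), Itgae (-2.09), Fam213a (-2.07) and Cldnd1 (-1.94). The IL-33 receptor Il1rl1 fell from 5.66 ± 1.63 to 0.465 ± 0.192 RPKM, and Gata3 fell by 0.86 and Ikzf2 by 1.04 on the log2 scale. Il2ra fell by 0.36 (adjusted p = 0.00993), and Foxp3 by 0.29 (adjusted p = 0.0373). The Foxp3 call was lost without any 1 of stimulated WT libraries 2 and 3, the 3 stimulated KO libraries or unstimulated WT library 2 (adjusted p from 0.0523 to 0.157), without the filter (0.0642), with a replicate block over the 12 libraries (0.0583) and with a term for Y-linked transcripts (0.0827). It was also lost without the 4 libraries that hold them, where WT library 3 alone stands for WT. Without stimulated KO library 3 the adjusted p of Il2ra was 0.0564, and without stimulated KO library 2 that of Itgae was 0.0518 (0.137 without the 4 libraries with Y-linked transcripts). The rises included Wnt10a (2.15), the glucose transporter family member Slc2a6 (2.07), the serine protease inhibitors Serpina3g (2.03) and Serpina3f (2.02), Igfbp7 (2.02), Cd80 (1.87), Il2 (1.86) and Gbp5 (1.79). Serpina3f and Serpina3g share a start coordinate and similar sequence, so reads may be split between them. The microRNA gene Mir6973a (2.32) lies inside Ltb on the same strand, and Ltb rose as well, from 264 ± 37.8 to 493 ± 42.5 RPKM. Il2, the cytokine that Treg cells mostly take up from other T cells, was at 6.86 ± 0.606 in WT and 30.8 ± 15.6 RPKM in KO.

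**Figure D2:**
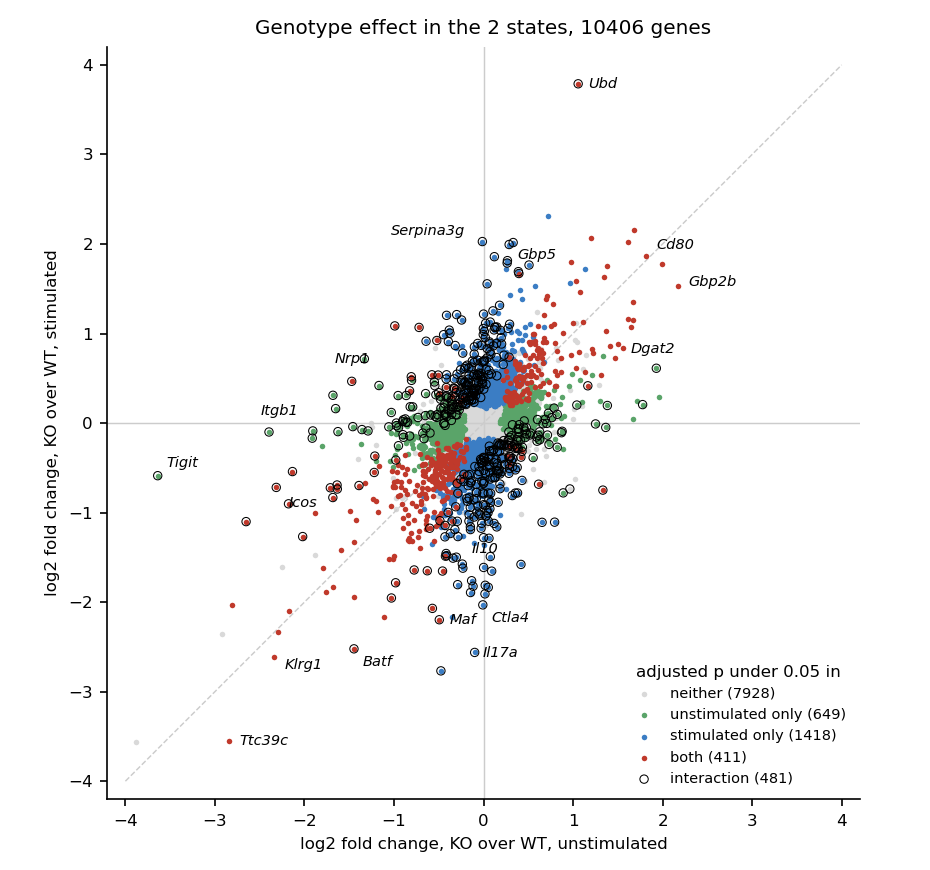
log2 fold change of KO over WT without stimulation (x axis) and with stimulation (y axis) for the 10406 tested genes, coloured by the contrast in which they passed an adjusted p of 0.05; circles mark genes whose genotype effect differed between the states. Of the genes called in both contrasts, 146 were higher in both, 243 lower in both and 22 went opposite ways.

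The effector and tissue Treg list was again lower, with 20 of 30 genes falling and 2 rising (21 and 2 adjusted over the list alone; camera adjusted p = 3.19e-13, and adjusted p = 0.0621 with an estimated correlation). In the Treg core list 11 of 27 fell and 3 rose (11 and 4 adjusted over the list alone), the falls including Gpr15 (-2.03) and Tgfb1 (-0.44). Its adjusted p was 0.0029, or adjusted p = 0.739 with an estimated correlation. The Th17-type list had 6 of 11 lower and 0 higher (7 and 1 adjusted over the list alone), among them Il17a, Il17f (-1.83) and Ahr (-0.96). It kept its call both ways (adjusted p = 3.56e-05, and adjusted p = 0.0425 with an estimated correlation). Chemokine receptors, integrins and trafficking genes, called without stimulation, were not called with it (11 of 27 lower and 6 higher, 12 and 6 adjusted over the list alone, adjusted p = 0.124). Interferon response genes were higher, with 13 of 28 rising and 0 falling (18 and 0 adjusted over the list alone). They included the GTPases Gbp5 (12.6 ± 1.91 to 45.5 ± 2.95 RPKM), Gbp6 (5.21 ± 0.11 to 12.0 ± 0.823), Igtp (204 ± 8.06 to 297 ± 9.14) and Irgm1 (95.3 ± 4.53 to 150.4 ± 2.91). This list also kept its call (adjusted p = 1.98e-11, and adjusted p = 0.0478 with an estimated correlation). Oxidative phosphorylation had 14 of 43 genes higher and 0 lower (28 and 2 adjusted over the list alone; adjusted p = 4.95e-07, and adjusted p = 0.471 with an estimated correlation). Changes were small, such as Atp5b at 0.29 and Cox4i1 at 0.29 on the log2 scale. The call of Atp5b was lost without WT library 2 or 3 or KO library 1 or 3 (adjusted p from 0.0548 to 0.0754), with the 6 libraries fitted alone (0.0546) and without both KO libraries numbered 1 (0.0682). That of Cox4i1 was lost without WT library 3 (0.0639), KO library 3 (0.0666) or both KO libraries numbered 1 (0.0551). Amino acid transport, serine and one-carbon genes had 6 of 24 higher and 0 lower (11 and 0 adjusted over the list alone), led by Slc43a1 (1.17), with an adjusted p of 0.000166, or adjusted p = 0.397 with an estimated correlation. Cell cycle genes had 2 of 36 higher and 1 lower and the list was not called (adjusted p = 0.824). No lipid list was called, with 4 higher and 1 lower of 21 triglyceride genes (the same adjusted over the list alone, adjusted p = 0.887), 5 and 5 of 28 fatty acid oxidation genes (8 and 7, adjusted p = 0.785) and 1 and 0 of 13 fatty acid synthesis genes (0 and 0, adjusted p = 0.824). Of the triglyceride genes, Dgat2 was higher (0.88) and Dgat1, the other enzyme of the last step of synthesis, was lower (-0.68). Of the genes listed for other cells, Lyz2 was at 0.165 ± 0.183 in WT and 0.145 ± 0.25 RPKM in KO after stimulation, and Cd74 was higher in KO, at 33.5 ± 4.47 against 22.8 ± 0.553 RPKM (log2 fold change 0.53, adjusted p = 0.0229). The Cd74 call was lost without WT library 2 or 3 or KO library 1 or 3 (adjusted p from 0.057 to 0.0862), without the filter (0.0601) and without the 4 libraries with Y-linked transcripts (0.157), and no list of other cells was called.

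In all, 808 genes were higher and 1021 lower in stimulated KO (17.6% of 10406), of which 73 and 115 changed by at least 1 on the log2 scale. Leaving out any 1 stimulated library except WT library 1 lowered the count of higher genes to between 406 and 513, and leaving out WT library 2 or 3 or KO library 2 or 3 lowered that of lower genes to between 588 and 652. Leaving out the 4 libraries with Y-linked transcripts gave 633 lower genes and ended 9 of the 83 named calls and values checked, and the balance turned with rescaling by median ratios (988 higher and 900 lower) and with limma-voom (1193 and 1054).

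The genotype effects of the 2 states were compared, since the contrasts share no library. Cd80, Wnt10a, Igfbp7, Plac8 and Gbp2b were among 146 genes higher in KO in both states, where 35.2 would be shared by independent lists. Ttc39c, Klrg1, Itgae, Cxcr6, Gpr15 and Batf were among 243 genes lower in both, where 59.6 would be shared. If the same number in the 2 states marks the same animal, which the labels leave open, the lists are not independent. Within each genotype, the deviations of every unstimulated library from its group mean correlated best with the stimulated library of its own number (0.075 to 0.274). The WT numbers with Y-linked transcripts were also the same in both states. Both contrasts share 1 estimate of spread per gene, so the lists are not fully independent in any case. Another 22 genes were called in opposite directions, including Nrp1, at -1.47 without and 0.47 with stimulation, the latter lost without stimulated WT library 2 (limma adjusted p = 0.0525), with a term for Y-linked transcripts (0.38, adjusted p = 0.0662) and without the 4 libraries that hold them (0.32, adjusted p = 0.234). Over the 2478 genes called in either contrast, Pearson's r of the log2 fold changes was 0.53 and Spearman's rho was 0.53. These correlations are across genes, which are not independent replicates. Genes called in the same direction numbered 389 in all, 254 when each contrast was fitted on its own groups, 47 without the 4 libraries with Y-linked transcripts, and 251 and 253 without unstimulated WT library 1 or 3.

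The interaction asked which genotype effects differed between the states. Tigit was 121 ± 10.4 against 9.89 ± 6.39 RPKM without stimulation and 136 ± 14.1 against 90.3 ± 11.8 RPKM with it, WT before KO, so most of the gap closed (interaction log2 fold change 3.05, SE 0.38, limma adjusted p = 0.00062). Itgb1 went from 120.5 ± 10.7 against 22.1 ± 1.94 RPKM to 42.3 ± 4.39 against 39.2 ± 0.69 RPKM (2.29, SE 0.13, adjusted p = 8.97e-07). Ctla4 showed the reverse, with 136 ± 24.9 against 136 ± 26.0 RPKM without and 213 ± 33.3 against 51.0 ± 4.24 RPKM with stimulation (-2.02, SE 0.21, adjusted p = 0.000174). Maf (-1.70), the TACI receptor gene Tnfrsf13b (-1.61), Fam213a (-1.50), Il17a (-2.46) and Il17f (-1.89) lost RNA relative to WT after stimulation. Il17a and Il17f had at most 3 reads in any unstimulated library, too few to measure a genotype effect there. Their interaction mostly restates the difference between stimulated cells. Serpina3g (2.04), Ubd (2.73), Nrp1 (1.94), Gbp5 (1.52), the trafficking factor Klf2 (1.28) and the death receptor Fas (0.81) gained RNA relative to WT. Ubd was already higher in unstimulated KO, at 1.01 to 2 RPKM against 0.09 to 0.2 in unstimulated WT. The log2(RPKM + 1) scale understates that difference, which raises the interaction of Ubd.

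Some of these calls were fragile. Il2 (1.74, adjusted p = 0.0364) and Il1r2, the decoy IL-1 receptor (-1.76, adjusted p = 0.0208), were lost without WT library 2 or 3 of the unstimulated group and without KO library 2 or 3 of the stimulated group (adjusted p of Il1r2 from 0.0534 to 0.0582, and 0.0626 without the filter). The call of Il2 held only where stimulated WT library 1 or stimulated KO library 1 was the library left out, and the adjusted p was from 0.0516 to 0.0895 without any other, 0.228 with the smaller pseudocount and 0.0902 without the filter. Batf itself had an interaction of -1.07 (adjusted p = 0.0243), which was lost without unstimulated WT library 2 or 3, stimulated WT library 2 or stimulated KO library 2 or 3 (adjusted p from 0.055 to 0.0673), and without the filter (0.0653). Snord42b (-2.08) is a 55 base RNA inside Rpl23a on the same strand, was listed at 0 in unstimulated WT, and was not called by limma-voom on reads, nor were Ubd, Il2, Il17a and Il17f. Without the 4 libraries with Y-linked transcripts 25 of the 48 named calls and values checked ended, with adjusted p of 0.15 for Tigit (2.81), 0.259 for Batf (-1.14), 0.233 for Il1r2 (-1.92), 0.311 for Il2 (1.76), 0.165 for Gbp5 (1.19), 0.112 for Klf2 (1.05), 0.181 for Fas (0.72), 0.0878 for Tnfrsf13b (-1.51), 0.0507 for Ubd (2.70) and 0.0625 for Il17f (-2.22).

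Of the interaction genes, 282 were called between genotypes with stimulation only, 120 without it only, 36 in both states in the same direction, 22 in both in opposite directions and 21 in neither. The interferon response list was higher (6 of 28 genes higher and 0 lower, 10 and 0 adjusted over the list alone, camera adjusted p = 3.66e-07, and adjusted p = 0.256 with an estimated correlation). The cell cycle list was lower, with Ube2c at -0.67 among 4 of 36 genes lower and 0 higher (10 and 0 adjusted over the list alone, adjusted p = 3e-07, and adjusted p = 0.498 with an estimated correlation). The Th17-type list was lower (3 of 11 lower and 1 higher, 5 and 1 adjusted over the list alone, adjusted p = 0.0396, and adjusted p = 0.256 with an estimated correlation). In all, 247 genes had a higher and 234 a lower KO effect after stimulation (4.6% of 10406). Leaving out any 1 unstimulated WT library, stimulated WT library 2 or stimulated KO library 2 or 3 lowered these counts to between 107 and 152 and between 99 and 143, leaving out stimulated WT library 3 gave 155 lower, and leaving out the 4 libraries with Y-linked transcripts gave 9 and 15. Rescaling by median ratios gave 217 and 239.

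After stimulation, WT cells held less RNA for Fos, Foxp3, Tcf7 and Cpt1a and more for Ccl3, Ccl4, Tfrc and Odc1 than without it. The labels give the 48 h, the antibodies and IL-2 for the stimulated libraries only. Effects of receptor stimulation, of 48 h in culture and of IL-2 therefore cannot be told apart in the stimulation contrasts. Fos, an immediate early AP-1 gene, fell from 644 ± 36.6 to 2.90 ± 0.206 RPKM (n = 3, log2 fold change -7.37, SE 0.12, limma adjusted p = 1.14e-13). The chemokine genes Ccl3 (0.332 ± 0.14 to 239.6 ± 20.4 RPKM) and Ccl4 (1.27 ± 0.68 to 241 ± 31.0) and the transferrin receptor gene Tfrc (5.96 ± 0.799 to 180.2 ± 8.03) rose. Odc1, the first enzyme of polyamine synthesis, rose from 76.0 ± 2.21 to 1012 ± 76.4 RPKM. Ccr8, Il10, Irf4 and Il2ra rose by 2.76, 2.52, 2.69 and 1.19 on the log2 scale, and Foxp3 fell by 1.03, Tcf7 by 1.98 and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, by 1.22.

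Further large changes were falls of Ms4a4b (-7.05), Jchain (-5.82), Ifit1bl1 (-5.79), S100a4 (-5.69) and Cd7 (-5.42) and rises of the desaturase Scd1 (5.13) and the metallothionein Mt1 (4.74). Cell cycle genes rose in 35 of 36 cases and fell in 1, for example Plk1 (3.05) and Ccnb1 (2.67). Ribosome biogenesis had 24 of 25 higher and 0 lower (Myc 2.32, Gar1 2.12), and nucleotide and polyamine synthesis 23 higher and 2 lower of 25 (Rrm2 2.54, Srm 2.98). Amino acid transport, serine and one-carbon metabolism had 22 of 24 higher and 0 lower (Slc7a5 2.62, Shmt2 2.38), cholesterol synthesis 21 of 23 and 0 (Idi1 2.62, Cyp51 2.58), and fatty acid synthesis 12 higher and 1 lower of 13 (Fads2 4.59, Fasn 2.10). Glycolysis had 16 higher and 4 lower of 23 (Hk2 2.69, Slc2a1 1.98, Pkm 1.15), and cytokines 19 higher and 7 lower of 29 (Il3 3.71, Lta 2.79). The naive and central T cell list had 18 lower and 1 higher of 20 (Klf2 -3.78, S1pr1 -3.20), chemokine receptors, integrins and trafficking 21 lower and 3 higher of 27 (Ccr2 -3.47, Itgb7 -2.60), and interferon response 24 lower and 4 higher of 28 (Ifit1 -3.28, Isg20 -3.04). Markers of other cells fell too, in 12 of 12 B cell genes (Cd79b -3.20), 6 of 8 CD8 T cell genes (Cd8b1 -1.59), 7 of 8 NK cell genes (Tyrobp -3.37), 9 of 14 myeloid genes with 1 rising (Lyz2 -3.97), and 7 of 9 conventional CD4 T cell genes with 1 rising (Igfbp4 -3.97). These 16 lists were called by camera with adjusted p of at most 0.0388, and the counts adjusted over the list alone were the same except for myeloid genes (11 lower). With an estimated correlation no list was called, the smallest being chemokine receptors, integrins and trafficking (adjusted p = 0.0526 with an estimated correlation), and the others had adjusted p from 0.151 to 0.323 with an estimated correlation. For the trafficking list the estimate was 0.005, under the preset 0.01, so a higher correlation does not account for its lost call.

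**Figure D3:**
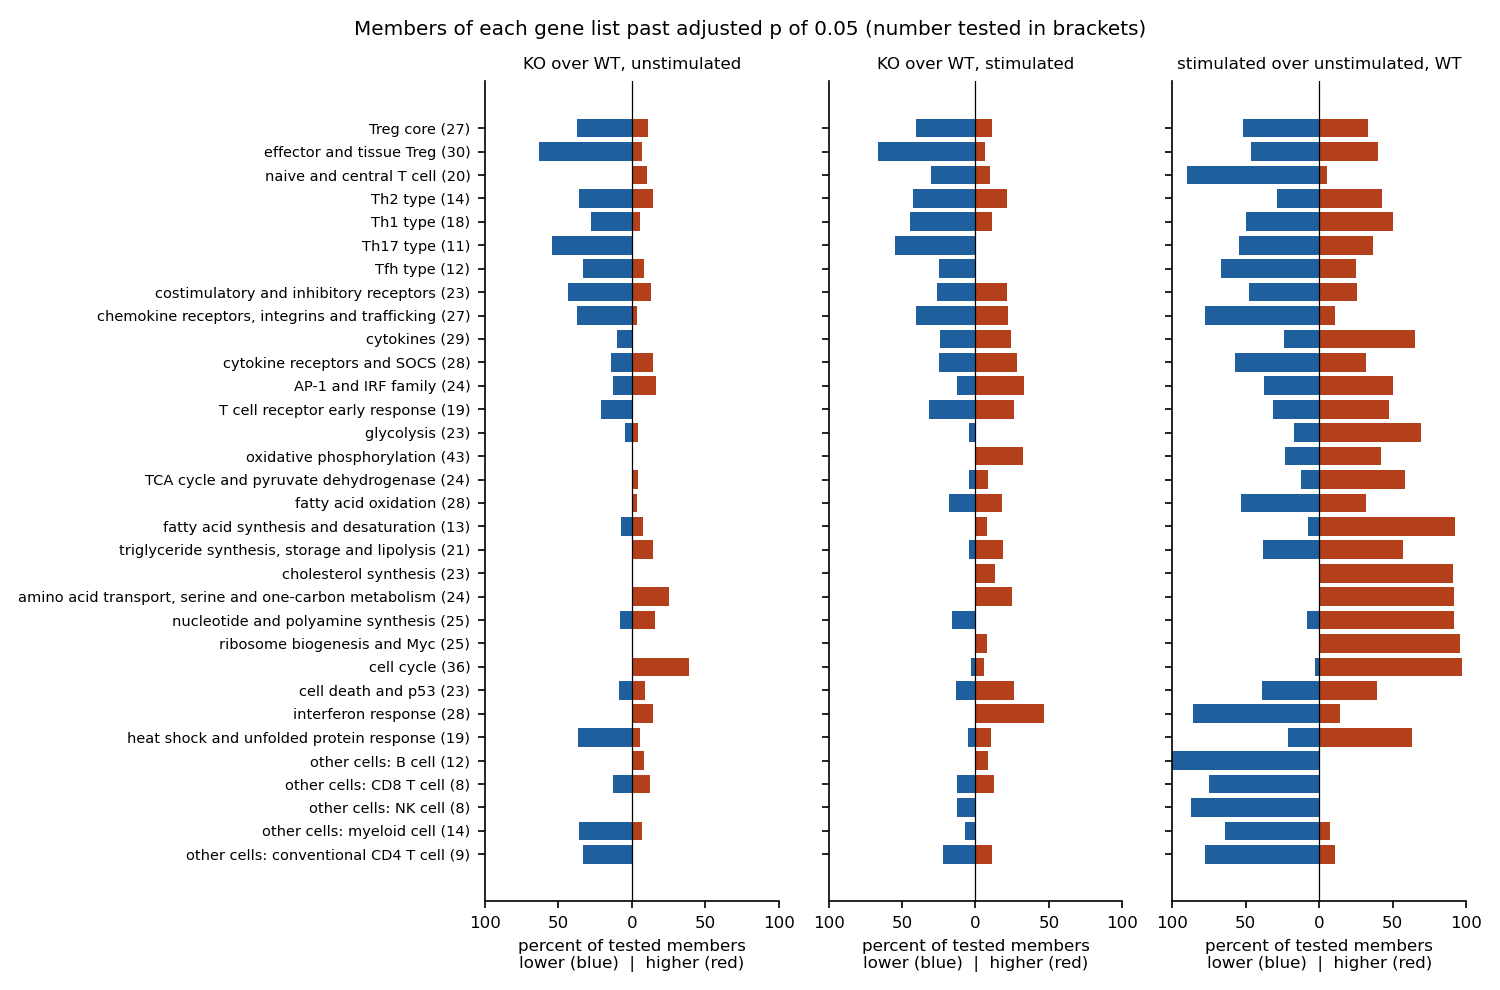
Percent of tested members of each gene list that were higher (right of 0) or lower (left of 0) at an adjusted p under 0.05 in 3 contrasts, with the number tested in brackets. Without stimulation 19 of 30 effector and tissue Treg genes were lower in KO, with stimulation 20 of 30, and in WT 35 of 36 cell cycle genes were higher after stimulation.

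In all, 4630 genes were higher and 3686 lower after stimulation in WT (79.9% of 10406), of which 1802 and 1468 changed by at least 1 on the log2 scale. The median log2 fold change over all genes was 0.11, and rescaling by median ratios shifted it by -0.10, so small changes are relative to that level.

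In KO cells, Fos, Ccl3 and Ms4a4b differed between the stimulated and unstimulated libraries in the same direction as in WT. Fos fell from 578 ± 74.9 to 4.09 ± 0.868 RPKM (n = 3, log2 fold change -6.83, SE 0.12, limma adjusted p = 2.05e-13), and Ccl3 rose from 0.331 ± 0.0523 to 161.7 ± 45.5 RPKM. Ms4a4b fell by 6.53, and Ccl4, Tfrc and Fads2 rose by 6.96, 4.34 and 4.53 on the log2 scale. Egln3, an oxygen-sensing prolyl hydroxylase, rose from 0.963 ± 0.295 to 54.4 ± 11.4 RPKM. Il2 rose from 0.146 ± 0.0121 to 30.8 ± 15.6 RPKM. Ctla4 fell from 136 ± 26.0 to 51.0 ± 4.24 RPKM in KO and rose from 136 ± 24.9 to 213 ± 33.3 RPKM in WT.

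Of the genes tested, 4605 were higher and 3597 lower after stimulation in KO (78.8% of 10406), and 1733 and 1337 changed by at least 1 on the log2 scale. Called in both genotypes were 4214 higher and 3242 lower genes, where independent lists would share 2049 and 1274, and 37 went opposite ways. Across genes, Pearson's r of the log2 fold changes was 0.957, and the slope of KO on WT was 0.912. The same 16 lists were called as in WT, and none with an estimated correlation (smallest adjusted p = 0.146 with an estimated correlation). Cell cycle genes again rose in 35 of 36 cases, cholesterol synthesis in 21 of 23 (22 adjusted over the list alone) and ribosome biogenesis in 24 of 25. Chemokine receptors, integrins and trafficking had 18 lower and 6 higher of 27, and interferon response 21 lower and 5 higher of 28. Median-ratio rescaling shifted the median log2 fold change of 0.12 by -0.11. By the correlation bound the numbers of the KO libraries paired unstimulated with stimulated samples, which the labels do not state. A fit with blocks of genotype and number, WT ones included, gave 4651 higher and 3626 lower.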

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

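The tests of KO library 1, of unresponsive cells and of splits that kept numbers together were chosen after the results were seen, and the others in this part were set before. The genotype effect differed between the states, by the interaction test of limma, for 247 genes with a higher and 234 with a lower KO effect after stimulation. The interaction log2 fold changes were 3.05 for Tigit, 2.73 for Ubd, 2.29 for Itgb1, 2.04 for Serpina3g, 1.94 for Nrp1 and 1.74 for Il2. They were -2.08 for Snord42b, -2.02 for Ctla4, -1.76 for Il1r2, -1.70 for Maf, -1.61 for Tnfrsf13b and -1.50 for Fam213a. Il2 had at most 4 reads in any unstimulated library, and Il2, Ubd and Snord42b were not called by limma-voom on reads. Of 100 drawn splits of both sets of 6 libraries, out of 200, 2 gave as many genes, the real one included (481 genes, highest other 611). The split with 611 kept the stimulated libraries parted by genotype and mixed the unstimulated ones, while the 81 splits that mixed both states called at most 1 gene. For gene lists, 92 of the 100 splits gave as many as the 3 called (highest other 14), so chance cannot be excluded. For the 389 genes called the same way in both genotype contrasts, 1 of 100 splits gave as many (highest other 0). Splits that mix both states also remove any genotype effect, so they cannot set an interaction apart from a genotype effect, and chance is not excluded for the interaction count. The splits also regrouped each state on its own. For the shared genes, chance can be excluded only if the same number in the 2 states does not mark the same animal. The labels leave this open, although within each genotype every unstimulated library correlated best with the stimulated library of its own number. Of the 10 splits that kept libraries of the same genotype and number together, 1 gave as many interaction genes as the real 481 (highest other 0), 7 as many lists as the real 3 (highest other 6) and 1 as many shared genes as the real 389 (highest other 0). These 10 are too few for a share under 0.05.

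The 10 splits of 6 libraries are too few for a share under 0.05 in the other contrasts. In unstimulated cells the real split called 1060 genes and 12 lists between genotypes (highest other 2 genes and 11 lists), and 1 split of 10 gave as many of either. In stimulated cells it called 1829 genes (highest other 1), as 1 split did, and 6 lists (highest other 11), as 6 splits did. Stimulation gave 8316 genes and 16 lists in WT (highest other 0 and 18) and 8202 genes and 16 lists in KO (highest other 0 and 17), with 1 split giving as many genes and 3 as many lists in each genotype. For the list counts between genotypes in stimulated cells and for stimulation, other splits gave as many or more, so chance cannot be excluded.

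The genotype calls were weighed against differences between libraries with and without Y-linked transcripts and against flanking DNA carried with the Batf deletion. WT library 3, which lacks Y-linked transcripts as KO libraries do, sat at a median of 0.055 of the way from WT libraries 1 and 2 to KO over 571 genes called without it in unstimulated cells, and at -0.069 over 994 genes in stimulated cells, which argues against the first as the main cause. Within 10 megabases of Batf, 13 of 87 tested genes were called in stimulated cells (odds ratio 0.82, 95% interval 0.42 to 1.5, Fisher's exact test, two-sided, p = 0.671), which argues against an excess of calls there. In unstimulated cells 9 were called (odds ratio 1.02, 0.45 to 2.04, exact p = 0.86), and the interval leaves an effect of flanking DNA on these genes and one of Batf that cannot be told apart. Loss of Batf stays open as a hypothesis for the remaining calls.

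Unstimulated KO library 1 was nearer WT than KO libraries 2 and 3 for Klrg1, at 14.67 against 3.77 and 7.21 RPKM, and Batf, at 46.91 against 32.99 and 25.94, while Il1rl1, at 12.21 against 3.06 and 3.15, lay above WT (6.18 to 7.74 RPKM), and its fall was called without KO library 1 (-0.91, adjusted p = 0.00939). Over 47 genes lower in KO libraries 2 and 3 its median share of the way back to WT was 0.138 (quartiles 0.008 and 0.289; Batf gave 0.265), but the genes were chosen on the libraries it was compared with, and libraries 2 and 3 in its place gave 0.001 and 0.008, so cells that kept Batf and a difference between animals cannot be told apart for these genes. Over 20 genes higher in those libraries the median was -0.282 (quartiles -0.759 and 0.064), and 0.281 and 0.357 with libraries 2 and 3 in its place, which argues against such cells for that part, as with Cd80 at 14 against 6.44 and 5.36 RPKM. The upper quartile over all 67 genes was 0.27, which argues against a WT library under a KO label. A difference between animals stays open and was not tested.

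Interferon response genes were higher in stimulated KO, with 13 of 28 called. Unresponsive KO cells, taken as cells that kept their whole unstimulated profile, would carry over their higher unstimulated levels. However, the 47 deepest-falling genes allowed 2.36% of such cells (upper quartile). The lower quartile of what the 13 members needed was 24.9%, and 5 needed over 100% or fitted no share. Cells that changed in culture or with IL-2 without responding to the antibodies, or that responded in part, were not modelled. The test cannot decide on those cells. WT library 3 sat at a median of 0.167 of the way to KO over the members, and 84.6% of them were nearer WT libraries 1 and 2, which argues against the Y-linked difference as the cause. Loss of Batf stays open as a hypothesis, and the list was called both with the preset and with the estimated correlation. Other technical sources were not tested.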

How the results depend on the processing

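The alternatives with median-ratio rescaling, limma-voom, a term for Y-linked transcripts, the 4 libraries with such transcripts left out and both KO libraries numbered 1 left out were chosen after the data were seen. Of 329 named gene and contrast pairs, compared in 23 settings as far as each fit held the gene and contrast, 0 reversed. Leaving out 1 library left 3776 comparisons as they were, ended 156 calls and added 16, and the other settings gave 3232, 158 and 18. The totals include contrasts that do not hold the library left out. There the fold change cannot move, and only the estimated spread can change a call. Pairs called in neither fit counted as the same whatever their sign, so these totals overstate how stable the calls were. Leaving out 1 library at a time, KO against WT without stimulation gave 239 (without WT library 3) to 574 (without KO library 2) higher and 326 (without WT library 1) to 868 (without KO library 2) lower genes. With stimulation it gave 406 (without KO library 3) to 1144 (without WT library 1) higher and 588 (without WT library 3) to 1270 (without WT library 1) lower. The interaction gave 107 (without stimulated KO library 3) to 279 (without stimulated WT library 1) higher, 99 (without stimulated KO library 3) to 329 (without unstimulated KO library 3) lower, and 2 (without stimulated KO library 1) to 6 lists (without stimulated KO library 2, and 5 without unstimulated KO library 1). Genes called the same way in both genotype contrasts numbered 251 (without unstimulated WT library 1) to 475 (without unstimulated KO library 2). Stimulation counts stayed within 1.5 times. Fitting only the compared groups gave 196 higher and 321 lower without stimulation and 254 shared genes, with fewer residual degrees of freedom. An adjusted p under 0.01 in both contrasts gave 160 shared. A term for Y-linked transcripts gave 399 lower without stimulation. Without the 4 libraries holding them, where WT library 3 alone is assumed to vary like the other groups, the counts were 41 higher and 57 lower without and 633 lower with stimulation, 9 and 15 for the interaction and 47 shared; fewer libraries lower them by construction. Without both KO libraries numbered 1, 298 were higher without stimulation and 6 interaction lists were called. An estimated correlation gave 1 and 2 lists for KO against WT without and with stimulation, and 0 for stimulation in WT, stimulation in KO and the interaction. Fry, which asks if a list moves and not if it moves more than other genes, gave 10 lists with stimulation between genotypes, 28 for stimulation in WT and 29 in KO. For the lists lost with an estimated correlation and for the other changes the cause was not tested. A replicate block over the 12 libraries gave 414 and 526, 701 and 914, and 194 and 179 higher and lower genes for the genotype contrasts and the interaction. It called Cd74 without stimulation (adjusted p = 0.0237) and not Foxp3 with it (0.0583). For stimulation in KO, blocks of genotype and number, WT ones included, gave 4651 and 3626. Of the WT pairs, 1 correlated under 0.1, although each unstimulated WT library correlated best with the stimulated one of its own number. This block changed no list or count by over 1.5 times. DESeq2 and edgeR alternatives planned for counts were not run, since the plan set limma for a table of RPKM, although the reads could be worked out from it. The smallest simulated change was recovered in 34% of genes, so changes of that size are mostly not detectable here.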

Other observations

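The tests here are those of the contrasts, and no further hypothesis was tested. Several lists held genes that moved both ways in stimulated KO cells and were not called. Of 24 AP-1 and IRF family genes, 8 rose and 3 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.228), with rises of Atf3 (log2 fold change 1.09), Irf1 (0.53) and Irf4 (0.51) and falls of Maf and Fosl2 (-1.16). Of 19 early genes of T cell receptor signalling, 5 rose and 6 fell (7 and 6 adjusted over the list alone, adjusted p = 0.994). Cd69, an activation marker, rose by 0.70 and Cd5, a brake on receptor signalling, by 0.54, while Nr4a2 fell by 1.27. Of 23 cell death and p53 genes, 6 rose and 3 fell (9 and 4 adjusted over the list alone, adjusted p = 0.124), including the proapoptotic Bcl2l11 (0.95), Fas (1.10) and Gadd45g (1.33). Of 20 naive and central T cell genes, 2 rose and 6 fell (2 and 8 adjusted over the list alone, adjusted p = 0.485), with Klf2 up by 1.67, the IL-7 receptor gene Il7r down (-1.29) and the egress receptor S1pr1 down (-0.78).

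Of 18 Th1-type genes, 8 fell and 2 rose in stimulated KO (8 and 2 adjusted over the list alone, adjusted p = 0.124). The master factor Tbx21 was at 72.3 ± 1.78 in WT and 56.3 ± 1.82 RPKM in KO (-0.35, adjusted p = 0.0305), a call lost without any 1 of the 6 stimulated libraries (adjusted p from 0.0566 to 0.0893), without the filter (0.0583), with a term for Y-linked transcripts (0.058), without the 4 libraries that hold them (0.237) and without both KO libraries numbered 1 (0.088). Ifng, at 96.3 ± 15.5 and 147 ± 75.9 RPKM, did not pass (adjusted p = 0.237), but was higher without KO library 1 (0.87, adjusted p = 0.00936). Of 14 Th2-type genes, 6 fell and 3 rose (6 and 4 adjusted over the list alone, adjusted p = 0.215), and of 29 cytokines 7 rose, among them Lif (1.06), and 7 fell (10 and 7 adjusted over the list alone, adjusted p = 0.743). Without stimulation, 4 of 12 Tfh-type genes fell, with Tox2 at -2.65, and 1 rose (4 and 2 adjusted over the list alone, adjusted p = 0.0978). Glycolysis had 1 of 23 genes higher and 1 lower without stimulation and 0 higher and 1 lower with it, the same adjusted over the list alone (adjusted p = 0.318 and 0.705). For every called list of the 5 contrasts the median, the mean and the test had the same sign. They differed in sign between genotypes without stimulation for early T cell receptor genes, triglyceride metabolism and cholesterol synthesis. With stimulation they differed for cytokine receptors, fatty acid synthesis, triglyceride metabolism, nucleotide synthesis, NK cell and conventional CD4 T cell genes. After stimulation they differed in both genotypes for effector and tissue Treg genes, costimulatory receptors and cell death, and in WT for Th17-type genes. In the interaction they differed for Treg core, effector and tissue Treg, Th1-type, cytokine, cytokine receptor, AP-1 and IRF, early T cell receptor, triglyceride, B cell, CD8 T cell and conventional CD4 T cell genes.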
